A study of Homo sapiens with 3 samples.

How the data were processed

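Single-cell RNA-seq had been carried out with a 10x Genomics Chromium dual index kit on human synthetic embryo models (SEMs), aggregates of pluripotent stem cells that are cultured outside the uterus. Per the labels' protocols, cells of WIBR3, a human embryonic stem cell line kept in a naive state, had been aggregated with wild-type cells induced under conditions named RCL or BAPJ, names that the sources used here do not spell out. The series holds 1 library for each of protocol days 4, 6 and 8, made from about 80 pooled models on day 4 and about 50 on days 6 and 8, with a target of 5000 cells per library. Whole models, extraembryonic parts included, had been dissociated with trypsin.

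Per the submitters' processing notes, the reads were processed with bcl2fastq, Cell Ranger 7.1.0 and Seurat 4.3.0 on genome build hg38. The annotation release, the handling of strand and any removal of doublets or free RNA were not given in the sources used here. The deposited raw table holds UMI counts (unique molecular identifiers, that is counted transcript molecules) of 28692 genes in 16582 cell barcodes, which the authors had not normalized. Values of the authors' normalized table are the natural log of 1 plus the counts scaled to 10000 per cell, for 12190 of the barcodes, and they differed from values recomputed from the raw counts by at most 7.4e-07. For the same cells, the deposited annotation gives the total count, the number of detected genes, the percent of counts in 13 mitochondrial genes, the library, 1 of 13 clusters and 1 of 16 curated labels. Checked on the files, the annotated cells were the barcodes with over 1000 and under 8000 detected genes and under 15% mitochondrial counts, and 0 of the 4392 barcodes without annotation met those limits.

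Libraries were grouped by protocol day, with 1 library per day, so no test, p-value or standard error was computed, and cells were not treated as replicates. By their names, the 16 curated labels were merged into 6 compartments: epiblast (4 labels), extraembryonic mesoderm (5 labels, ExEM in the annotation), yolk sac (2 labels, YS), secondary yolk sac (1 label, SYS), amnion (1 label) and trophoblast (3 labels, which include cytotrophoblast, CTB, and syncytiotrophoblast, STB). That reading of the abbreviations was not stated in the sources used here. Shares of cells were computed per day with exact Clopper-Pearson 95% intervals. For a share of 0, the limit given in the text is the share that 3 cells would make, which is lower than the exact upper bound.

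Raw counts were summed per day over all annotated cells, per compartment and per label, and expressed as CPM (counts scaled to a common total of 1000000), with exact Poisson 95% intervals. Ratios of days were given with exact conditional-binomial 95% intervals wherever a compartment had at least 50 cells on both days. Against a count of 0 the fold was computed from a floor of 3 counts and is given as a lower bound ("at least"). The exact 95% bound of such a fold lies nearer to 1 than the value given. Every interval covers counting error only. A list member counted as measured with at least 10 CPM on the higher day, and as higher or lower when its ratio was at least 2-fold with an interval that excluded 1. For each list with at least 3 measured members the median log2 ratio was computed, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, and with a 95% counting interval from 1000 Poisson draws. The percentile describes these libraries and is not a test. A median was given a direction from an absolute value of 0.5.

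The 12 marker lists and 18 pathway lists, the rule for named genes, the co-detection sets and the first set of alternatives were chosen before the data were examined. Named genes were the 10 with the highest and the 10 with the lowest ratio, ranked by the interval bound nearest to 1, among genes with at least 50 CPM on the higher day. Mitochondrial, ribosomal protein, unnamed, XIST and Y-linked genes were left out of that ranking. Up to 4 members with the largest change were added from each list the text describes, as were members that went against the list. KLF17, HOXD4 and PEG3, which belong to the lists, had no entry under that symbol in the count table. Chosen after the data were seen were the merging of labels, the limit of 0.5 for a direction, the rule that contrasts compartments (lists with at least 5 measured members whose medians passed 0.5 in opposite directions), the day that stands for each co-detection set, the genes named from single labels, and the alternatives marked so in the closing section.

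Co-detection was the share of cells with a UMI of at least 3 genes of a set after every cell had been thinned at random to 5000 UMIs, with shallower cells left out. The sets were NANOS3, SOX17, PRDM1 and TFAP2C for germ cells, CER1, LHX1, DKK1, HHEX, LEFTY1 and NOG for anterior hypoblast, CGA, CGB3, CGB5, CGB8, SDC1, CYP19A1 and ERVW-1 for syncytiotrophoblast, and TBXT, MIXL1, EOMES, MESP1 and GSC for primitive streak. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold called 2 cells on day 4, 0 on day 6 and 0 on day 8, which is too few for a caller that works, so leaving out the 5% of cells with the highest score was added as an alternative. Cells were kept in the main values whatever their score. Leaving out the called cells was an alternative as well.

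Alternatives were TMM factors from edgeR 4.0.16 in R 4.3.3, totals without mitochondrial and ribosomal protein genes, the mean of per-cell CPM, no filter on low values, the mean of the authors' normalized values, equal weight of compartments, a stricter cell filter (at least 2000 genes and at most 10% mitochondrial counts), compartments taken from Leiden clusters (leidenalg 0.10.2, resolution 1), 2 set genes and thinning to 2000 UMIs. Equal weight of labels inside a compartment, leaving out the cells in a Leiden cluster whose most frequent compartment is another one, and equal weight of the Leiden clusters with at least 50 cells of the compartment on both days were added after the data were seen. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

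The code was tested on simulated counts with 200 genes changed by known folds. For day 8 over day 4 in all cells, 95.3% of the intervals of 9640 unchanged genes held the true ratio, and the ratio was at least 2-fold for 100.0% of 48 genes simulated 4-fold higher and for 39.6% of 53 genes simulated 2-fold higher. In the epiblast, the intervals of 95.6% of 8979 unchanged genes held it. In the secondary yolk sac, with the fewest cells tested, 95.8% of 8960 intervals did, but 1.41% of the unchanged genes there were called at least 2-fold different, against 0% in the other 2 tests. Gene coordinates are those of the GRCh38 annotation supplied for this work, matched by symbol. Barcodes without annotation entered no comparison and are described in the closing section.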

Results

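The 3 libraries show which cell types the synthetic embryo models held on protocol days 4, 6 and 8, and how gene expression differed between those days in the models as a whole and inside each annotated cell type. Models from each day were pooled into 1 single-cell library, so that every comparison of days sets 1 pool of models against another and has no replicate. The annotation covered 2957 cells on day 4, 5991 on day 6 and 3242 on day 8. Those cells held 36135121, 56211665 and 31485168 UMIs in turn, with medians of 10710.0, 8418 and 7934.5 UMIs and 3729, 3287 and 3199 detected genes per cell. The median mitochondrial share of counts was 5.29%, 5.73% and 5.06%. Intervals are 95% intervals and cover counting error only.

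Composition differed most in the balance of epiblast, the tissue that forms the embryo proper, and extraembryonic mesoderm, the connective tissue that lines the yolk sac and amnion. Epiblast cells made up 55.1% of the day 4 library (53.3 to 56.9%), 28.1% of day 6 (27.01 to 29.3%) and 18.4% of day 8 (17.03 to 19.7%). Extraembryonic mesoderm went the other way, from 16.5% (15.2 to 17.9%) through 40.6% (39.3 to 41.8%) to 64.1% (62.4 to 65.8%). There were 0.299 extraembryonic mesoderm cells per epiblast cell on day 4, 1.44 on day 6 and 3.49 on day 8. Yolk sac cells took the largest share on day 6, 24.6%, against 17.96% on day 4 and 9.07% on day 8. Secondary yolk sac cells made up 2.27%, 4.02% and 4.32%, and amnion cells 3.18%, 2.62% and 4.01%. These smaller shares depended on the labels: with compartments taken from clusters of this work, secondary yolk sac held 9.19% and yolk sac 3.86% of day 8, and amnion 6.43% of day 4. Trophoblast labels were carried by 147 cells on day 4 (4.97%, 4.22 to 5.82%), by 0 of 5991 cells on day 6, which allows a share of up to 0.0501%, and by 4 cells on day 8 (0.123%, 0.0336 to 0.316%). Of the day 4 trophoblast cells, 100 were labelled syncytiotrophoblast-like, 31 cytotrophoblast-like and 16 trophoblast.

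**Figure D1:**
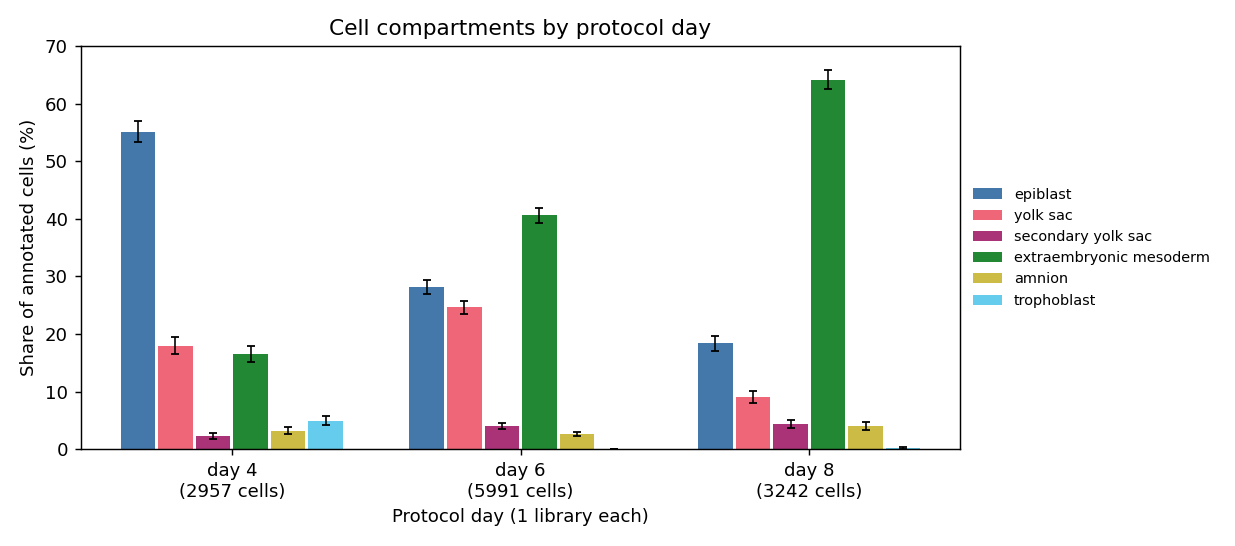
Share of annotated cells (percent of the library) in each of the 6 compartments on protocol days 4, 6 and 8, with exact 95% binomial intervals as error bars and 1 library per day. The epiblast share is highest on day 4 (55.1%) and the extraembryonic mesoderm share on day 8 (64.1%).

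The labels inside the compartments were mixed differently as well. In the epiblast, the label Epiblast_1 held 41.1% of the cells on day 4, 39.7% on day 6 and 24.0% on day 8, while Commited_Epiblast_3 held 23.7%, 13.9% and 46.6%. The label ExEM_4 made up 10.2% of extraembryonic mesoderm on day 4, 21.8% on day 6 and 3.94% on day 8. YS_2 made up 26.2%, 50.6% and 24.2% of the yolk sac. YS_2 carried more RNA of the pluripotency factor POU5F1 than YS_1 on every day (877, 639.6 and 292 CPM against 165, 129.6 and 67.4 CPM), so that levels in the yolk sac compartment average labels that differ in this RNA. YS_2 cells also held more UMIs, with medians of 20179, 11218 and 17305 against 10111.5, 8029 and 8961 in YS_1. Whether doublets contributed to the POU5F1 level was not tested. Both labels were singled out after their values were seen.

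The epiblast and extraembryonic mesoderm lists were highest in the compartment of their name on all 3 days, the amnion list on days 6 and 8 and the trophoblast list on day 4. Most other lists have no compartment of their name. This describes the annotation, since some of those genes may have been used to name the labels. The epiblast list summed to 3987, 3876 and 2421 CPM in epiblast cells on days 4, 6 and 8. The hypoblast and yolk sac endoderm list was highest in the secondary yolk sac (20733, 26977 and 36358 CPM), with the yolk sac next (4465, 5266 and 14117 CPM). Extraembryonic mesoderm carried its own list at 2283, 3291 and 5894 CPM, and the cardiac muscle list at 846, 415 and 507 CPM. The amnion list was highest in amnion cells on days 6 and 8 (1449.6 and 2045 CPM), but on day 4 trophoblast cells had 1650.4 CPM against 1445 in amnion. No compartment held the primitive streak and nascent mesoderm list throughout: it was highest in the yolk sac on day 4 (114 CPM), in extraembryonic mesoderm on day 6 (322 CPM, with the yolk sac at 309) and in the epiblast on day 8 (105 CPM). With cells weighted equally, extraembryonic mesoderm was highest for that list on 0 days rather than 1.

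The comparison of days 8 and 4 over all cells asks how the whole model differed between the ends of the time course. The extraembryonic mesoderm, extracellular matrix and HOX lists were higher on day 8, and the syncytiotrophoblast, epiblast and naive pluripotency lists were lower. TTR, which encodes the transport protein transthyretin, was at 4.18 CPM on day 4 and 358 CPM on day 8, 85.7-fold higher (95% interval 72.99 to 101). The matrix genes POSTN (periostin), DCN (decorin) and COL6A3 were 44.8-fold (41.5 to 48.6), 31.6-fold (27.4 to 36.6) and 11.9-fold (10.97 to 13.04) higher. PDZRN4, CXCL14, SST, CNTN5, FOSB and LRRC7 completed the 10 highest genes, with ratios from 56.5 down to 12.8 for LRRC7, and each of these 6 had its highest compartment level in extraembryonic mesoderm. CGA, the shared subunit of the glycoprotein hormones, was at 3431 CPM on day 4 and 2.70 CPM on day 8 (1271-fold lower, 1028 to 1591). CGB3, a beta subunit of chorionic gonadotropin, had 1 UMI on day 8 against 62.5 CPM on day 4 (1969-fold lower, 353 to 77812). Its counts are uncertain in part, because the CGB genes on chromosome 19 are near-identical copies. The steroid enzyme genes CYP19A1 and CYP11A1 were 27.4-fold and 19.3-fold lower.

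MT1M, MT1H and MT1G, metal-binding metallothioneins that lie together on chromosome 16 (GRCh38, MT1M at 56632233 to 56633986, MT1G at 56666731 to 56668065, MT1H at 56669814 to 56671129), were 218-fold (142 to 352), 72.3-fold (64.2 to 81.8) and 55.5-fold (49.9 to 61.9) lower on day 8. They are close paralogs, so the split of reads between members is uncertain. SMPDL3B and the non-coding RNAs FOXD3-AS1 and LNCPRESS1 were 14.1-fold, 12.2-fold and 9.98-fold lower. For FOXD3-AS1, an antisense gene, the handling of strand in the counting was not given in the sources used here.

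Among the marker lists, 8 of 9 measured epiblast genes were at least 2-fold lower on day 8 and 0 higher (median log2 ratio -2.38, counting interval -2.41 to -2.31, percentile 0.0 among matched random lists). TDGF1, NANOG and POU5F1 were 7.08-fold, 6.59-fold and 4.26-fold lower, and SFRP2 only 1.55-fold. Of the extraembryonic mesoderm list, 13 of 13 were higher (median 2.66, 2.60 to 2.80, percentile 100.0). The homeobox genes of the HOX clusters, which pattern the body axis, were higher for 10 of 10 (median 2.76, percentile 100.0). Collagens and other extracellular matrix genes were higher for 10 of 15 (median 1.77, percentile 100.0), among them COL3A1 at 8.78-fold and COL1A2 at 7.57-fold. Mesenchymal genes (median 1.80), hypoblast and yolk sac endoderm genes (1.20) and cardiac muscle genes (1.11) were also higher. All 8 measured syncytiotrophoblast genes were lower (median -6.27, -7.14 to -5.61). The NODAL pathway, a signal of the pluripotent epiblast and the streak, had 6 of 9 members lower (median -1.83, percentile 0.0), with LEFTY1 16.8-fold lower, while CFC1 and PITX2 were 3.33-fold and 3.15-fold higher.

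Immediate early genes, which respond within minutes to growth signals, handling or dissociation, were higher on day 8 for 7 of 10 members of the immediate early and heat shock list (median 2.23, percentile 100.0). FOSB, FOS and JUN were 13.6-fold, 10.4-fold and 10.4-fold higher, and the heat shock gene HSPA1A 1.63-fold. Naive pluripotency genes were lower (median -2.15), with PRDM14, ZFP42 and DPPA5 5.03-fold, 4.68-fold and 4.21-fold lower and KLF5 1.49-fold higher. The primitive streak and nascent mesoderm list had a median of -1.10 over 3 measured members, but 1.21 with no filter on low values. Formative and primed pluripotency (-0.90), anterior hypoblast (-1.04), primordial germ cell (-1.06), trophoblast (-0.73), epithelial (-0.63) and S phase genes (-0.57) had lower medians. BMP targets (0.61) and the unfolded protein and amino acid response (0.68) had higher ones. Medians stayed within 0.5 of 0 for the amnion list (0.31), WNT targets (0.12), FGF and ERK targets (0.06), glycolysis and hypoxia (0.24), G2 and M phase (-0.16), p53 targets (0.00), imprinted genes (0.33) and the DNA methylation machinery (-0.18). Fewer than 3 members of the blood and endothelium and neural ectoderm lists were measured, so they have no median here. The median over all 10500 genes with at least 10 CPM was 0.09.

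These ratios mix differences in composition with differences inside cell types. When each compartment present on both days was given the same weight, the medians for day 8 over day 4 were -1.06 for the epiblast list, 1.28 for extraembryonic mesoderm, 1.41 for HOX, 1.38 for immediate early and heat shock, 0.50 for extracellular matrix, 0.54 for mesenchymal and 0.05 for hypoblast and yolk sac endoderm genes, and the cardiac muscle list changed sign to -0.53.

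Over all cells, day 6 differed from both other days in genes of gastrulation, the step at which the epiblast forms mesoderm and endoderm. All 6 measured primitive streak and nascent mesoderm genes were higher on day 6 than on day 4 (median log2 ratio 2.41, 2.24 to 2.51, percentile 100.0), and all 6 were lower on day 8 than on day 6 (median -2.67, -2.75 to -2.53, percentile 0.0). MESP1 was at 0.553, 13.9 and 5.81 CPM on days 4, 6 and 8, TBXT at 2.27, 13.6 and 5.24 CPM, MIXL1 at 14.6, 68.6 and 13.2 CPM and EOMES at 12.04, 43.5 and 5.62 CPM. The anterior hypoblast list, which holds secreted inhibitors of WNT and NODAL signalling, followed the same course (median 0.90 for day 6 over 4 and -1.97 for day 8 over 6). CER1 was at 5.37, 53.03 and 11.5 CPM and LEFTY1 at 12.8, 25.97 and 0.762 CPM, whereas SFRP1 was lower on each later day (114, 58.8 and 45.5 CPM). In the epiblast alone days 6 and 8 were closer: at 5000 UMIs per cell, TBXT had a UMI in 1.23% of cells on day 4, 8.55% on day 6 and 9.504% on day 8.

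From day 4 to day 6 the 10 highest genes were TTR (15.03-fold), POSTN (11.4-fold), SST, CER1 (9.88-fold), CNTN5, LHX1 (6.31-fold), GAL, APOA2 (4.91-fold), SLN and MIXL1 (4.69-fold). The 10 lowest were led by CGB3 (121-fold lower), CGA (46.3-fold) and CYP19A1 (32.96-fold) and included CYP11A1, IFI6, RHOBTB1, LUZP2 and the metallothioneins MT1M, MT1H and MT2A. Extraembryonic mesoderm genes were already higher on day 6 (10 of 12, median 1.58), and epiblast genes had a median of -0.57, with 1 of 9 at least 2-fold lower. The blood and endothelium list was measured with 3 members (median 1.66).

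From day 6 to day 8, TTR (5.70-fold), FOSB (4.93-fold), FOS (3.62-fold), POSTN (3.93-fold), DCN (3.72-fold), CCSER1, PRRX1, LEPR, EPHA7 and NTM were the 10 highest genes. CGA, MT1G, MT1H, LHX1, GAL, MIXL1, VRTN, MIR302CHG, CER1 and TDGF1 were the 10 lowest, with MIR302CHG, the host transcript of a pluripotency microRNA cluster, at 409.6 CPM on day 6 and 91.8 CPM on day 8. The median of the epiblast list was -1.62 and that of the NODAL pathway -1.65, against -0.04 between days 4 and 6.

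Over all cells with epiblast labels, the epiblast and naive pluripotency lists had lower medians on day 8 than on day 4, and the BMP target, WNT target and neural ectoderm lists had higher ones. SULF1, a sulfatase that modifies heparan sulfate, was at 3.24 CPM on day 4 and 59.3 CPM on day 8 (18.3-fold higher, 13.99 to 24.2). The imprinted gene DLK1 was 15.2-fold (12.98 to 17.8) higher, and IGFBP5, DACH1, ZFHX4, GLIS3, WLS and WNT5B were 15.8-fold, 14.01-fold, 13.5-fold, 12.5-fold, 10.2-fold and 9.51-fold higher. PLA2G2A and HAND1 were 17.98-fold and 14.5-fold higher, but their epiblast levels on day 8 were 7.21% of that in amnion and 5.98% of that in extraembryonic mesoderm. CGA was 463-fold lower; the UMIs behind its day 4 level occurred in every label of that day. The metallothioneins MT1M, MT1H, MT1G, MT2A, MT1E, MT1F and MT1X were 279-fold, 63.9-fold, 43.4-fold, 25.2-fold, 25.03-fold, 6.39-fold and 5.19-fold lower, with MT2A at 955 CPM on day 4 and 37.9 CPM on day 8. SMPDL3B and FOXD3-AS1 were 5.03-fold and 3.89-fold lower.

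Of the BMP targets, 6 of 9 were at least 2-fold higher on day 8 (median log2 ratio 1.31, 1.14 to 1.53, percentile 100.0), with MSX1 14.9-fold, MSX2 4.37-fold and ID1 2.94-fold higher (146 and 428 CPM for ID1), at 19.4%, 14.1% and 37.4% of their amnion levels. WNT targets were higher for 4 of 7 (median 1.30, 0.95 to 1.43, percentile 100.0), among them RNF43 (3.39-fold, at 14.3% of the amnion level) and NKD1 (3.17-fold, at 30.6% of the level in extraembryonic mesoderm), while AXIN2 was at 23.4 and 21.96 CPM. All 6 measured mesenchymal genes were higher (median 2.18), led by ZEB1 (13.7-fold) and CDH2 (5.76-fold). Lists of other cell types were higher too, extraembryonic mesoderm at 2.57 (2.03 to 3.08, 289 and 637 CPM in sum) and hypoblast and yolk sac endoderm at 2.68 (38.9 and 92.4 CPM). The amnion list had 4 of 5 members higher (median 1.78), including TFAP2A (3.43-fold) and TBX3 (3.14-fold), at 17.5% and 13.3% of their amnion levels. Epiblast genes had a median of -0.81 (4 of 9 lower), with DNMT3B 2.58-fold, L1TD1 2.05-fold and POU5F1 1.68-fold lower and SFRP2 2.02-fold higher. The naive pluripotency median was -0.78 and that of the NODAL pathway -0.91, with LEFTY1 6.64-fold lower. Formative and primed pluripotency genes had a median of 0.14, with CD24 1.83-fold lower. Immediate early genes were higher here as well (median 1.74, FOS 5.33-fold).

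Part of these epiblast values goes with cells that grouped elsewhere when all cells were clustered in this work. Of the epiblast cells, 81 on day 8 and 11 on day 4 fell in clusters with amnion as the most frequent compartment, and 462 and 1605 in epiblast clusters. With every cell in a cluster of another compartment left out, the medians for day 8 over day 4 were 0.75 for BMP targets, 0.82 for WNT targets, 0.91 for the amnion list, 1.32 for primitive streak and nascent mesoderm, 4.53 for neural ectoderm and -1.05 for the epiblast list. PLA2G2A and HAND1 were then at log2 ratios of 2.71 and 2.55 rather than 4.17 and 3.86. The clusters are built from the same expression values, so this alternative is no independent check of the labels.

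The epiblast clusters also differed between the days: the largest of day 4 held 697 epiblast cells then and 0 on day 8, and the largest of day 8 held 306, against 248 on day 4. In the 2 clusters with at least 50 epiblast cells on both days, given equal weight, most list medians were nearer to 0. BMP targets were at 0.47, WNT targets at 0.07, the amnion list at 0.29 and the epiblast list at -0.31, while naive pluripotency (0.44) and primitive streak and nascent mesoderm (-1.69) changed sign. Neural ectoderm (2.51), immediate early and heat shock (1.73), extraembryonic mesoderm (1.57) and mesenchymal genes (0.91) stayed higher, and the NODAL pathway lower (-0.66). The BMP and WNT target medians thus did not stay above 0.5 within clusters, although holding the cluster fixed also removes any change that moved cells between clusters.

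The neural ectoderm genes PAX6, SIX3 and LHX2 were each higher in day 8 epiblast, at 26.9, 32.8 and 11.5 CPM against 1.57, 4.77 and 0.442 CPM on day 4 (median log2 ratio 4.10, 3.59 to 4.67, percentile 100.0, and 2.55 with no filter on low values). The label Commited_Epiblast_3, looked up after these values were seen, held them at 68.3 (PAX6), 81.2 (SIX3) and 28.7 CPM (LHX2) on day 8, with POU5F1 at 85.96 CPM. TBXT, MIXL1 and EOMES were higher than on day 4 by 7.90-fold, 5.85-fold and 2.66-fold (median 2.55). In Posterior_Epiblast_2, chosen in the same way, TBXT was at 8.41, 61.4 and 71.3 CPM on days 4, 6 and 8. Of the primordial germ cell list, NANOS3 was 48.4-fold (22.6 to 124) and PRDM1 4.57-fold higher (PRDM1 at 15% of its secondary yolk sac level) while NANOG and PDPN were 2.001-fold and 1.96-fold lower (median -0.21). On day 8 the NANOS3 level in Posterior_Epiblast_2 was 51.8 CPM.

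**Figure D2:**
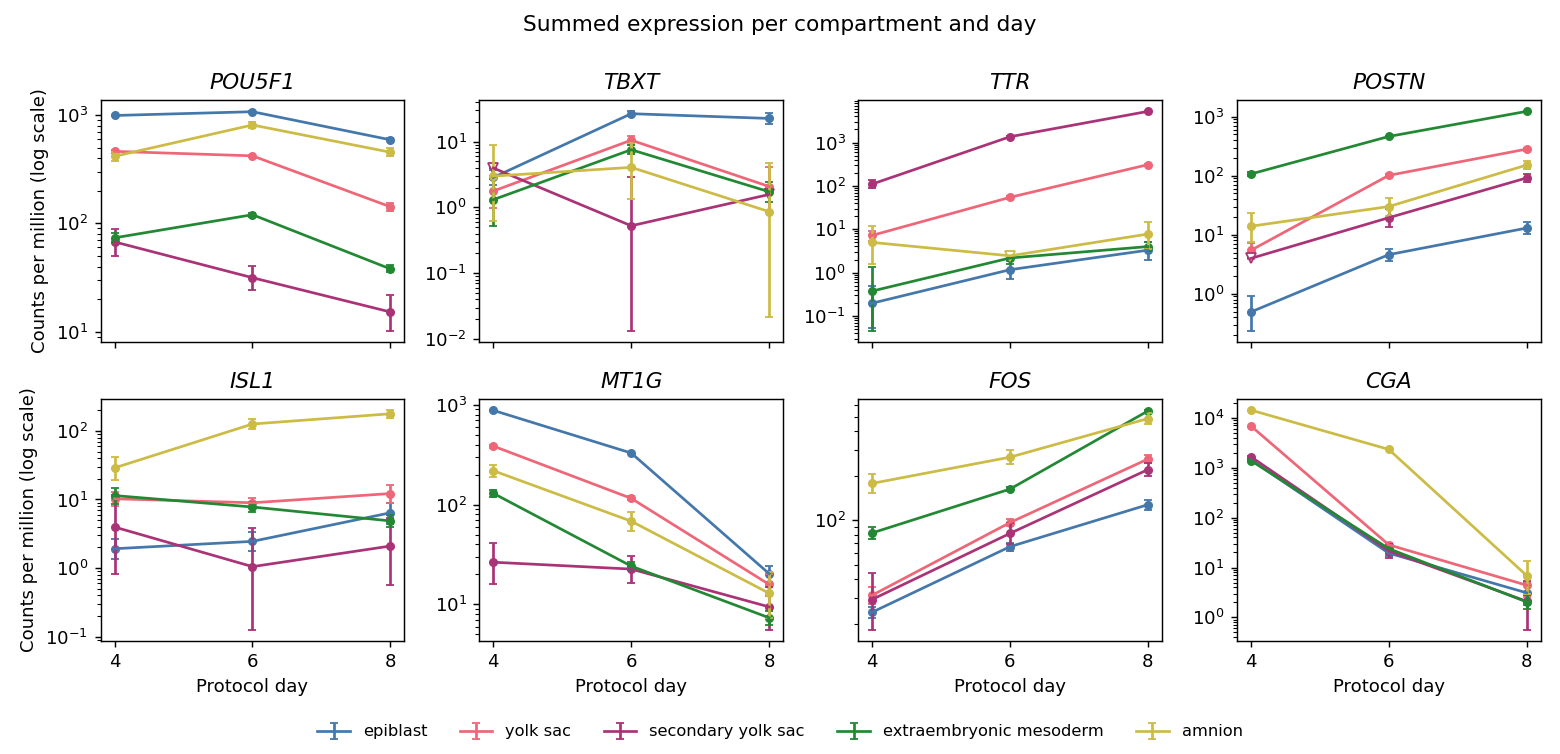
Levels of named genes (CPM, log axis) by protocol day in the compartments that held at least 50 cells on every day, so without trophoblast. Bars are exact Poisson 95% intervals, with 1 library per day. Open triangles mark 0 counts and are drawn at the level that 3 counts would give. CGA is lower on each later day in the compartments drawn, and TTR in the secondary yolk sac reaches 5236 CPM on day 8.

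The comparison of yolk sac cells asks how cells with that label differed between days 4 and 8. The apolipoprotein genes APOA1 and APOA2 were at 10482 and 2143 CPM on day 8, 3.18-fold (3.13 to 3.23) and 7.76-fold (7.40 to 8.14) higher, and APOB, AFP (alpha-fetoprotein) and TTR were 11.98-fold, 15.5-fold and 42.9-fold higher, although the day 8 levels of AFP and TTR were 6.56% and 5.91% of those in the secondary yolk sac. The hypoblast and yolk sac endoderm list had 7 of 14 members at least 2-fold higher (median log2 ratio 0.91, 0.80 to 1.01, percentile 100.0), whereas the transcription factor GATA4 was 2.47-fold lower. In YS_1 alone, TTR was at 10.4 and 403 CPM and APOA1 at 4657 and 14851 CPM on days 4 and 8. GNRH2, a gonadotropin-releasing hormone gene on chromosome 20, had 1 UMI on day 4 and 67.8 CPM on day 8 (536-fold higher, 95.4 to 21253). AKR1B10, ALDH1A1 and SLN were 45.4-fold, 20.8-fold and 17.5-fold higher.

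The higher median of the endoderm list did not hold for the yolk sac cells that clustered as yolk sac. In the clustering, 156 yolk sac cells of day 8 fell in clusters with secondary yolk sac as the most frequent compartment and 102 in yolk sac clusters, against 30 and 422 on day 4. On day 4, 45 more were in the trophoblast cluster and 26 in amnion clusters, against 0 and 7 on day 8. With every cell in a cluster of another compartment left out, the hypoblast and yolk sac endoderm list had a median log2 ratio of -0.29. The clusters are built from the same expression values, and this list was highest in the secondary yolk sac. Leaving out cells that clustered there tends to lower the list by construction, so that median does not decide whether yolk sac cells changed. TTR, AFP and ALDH1A1 were then at log2 ratios of 2.42, 1.64 and 2.30 rather than 5.42, 3.95 and 4.38. CYP11A1 and PGF stayed lower, at -5.13 and -2.61. The extraembryonic mesoderm list was at 2.64, extracellular matrix at 1.30, the epiblast list at -0.82 and the NODAL pathway at -0.83 in those cells.

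POSTN, CNTN5, SST and DCN were also among the 10 highest genes of the yolk sac (51.97-fold, 39.8-fold, 24.8-fold and 18.3-fold), at 22.9%, 39.9%, 31.9% and 26.6% of their level in extraembryonic mesoderm. The extraembryonic mesoderm list was higher for 12 of 12 (median 2.21), and extracellular matrix genes for 11 of 15 (median 1.36, percentile 100.0), with COL1A2 7.22-fold and FN1 2.57-fold higher. On day 8, 10% of the yolk sac cells held 40.6% of the COL3A1 and LUM UMIs of the compartment. Lower on day 8 were CGA (1556-fold), CGB3 (at least 164-fold), CYP11A1 (19.6-fold), PGF (5.01-fold) and the metallothioneins MT1M, MT1H, MT1G, MT1E, MT2A and MT1F (115-fold to 6.32-fold). The fold of CGA is that of a mixture, since on day 4 the 139 YS_2 cells held it at 14380 CPM and the 392 YS_1 cells at 1476 CPM. Epiblast genes had a median of -1.70 (7 of 9 lower), the NODAL pathway -1.26 (NODAL 2.45-fold lower) and S phase genes -0.73 (MCM5 2.34-fold lower). The immediate early and heat shock median was 1.87.

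Secondary yolk sac cells numbered 67 on day 4 and 140 on day 8, and TTR, AFP and RBP4 were among the genes with the highest ratios. TTR was at 109.9 and 5236 CPM (47.6-fold higher, 38.4 to 59.9), AFP at 41.05 and 1462 CPM (35.6-fold higher, 25.03 to 52.5) and RBP4, the plasma carrier of retinol, at 3.97 and 552 CPM (139-fold higher, 47.4 to 675, from 3 UMIs on day 4). FABP1, a fatty acid-binding protein gene, was 21.4-fold higher, and SULT1E1 and G0S2, with 0 UMIs on day 4, were at least 15.8-fold and 15.3-fold higher. APOA1 was high on both days (16688 and 19182 CPM). The endoderm regulators GATA4, SOX17 and GATA6 were 5.20-fold, 3.87-fold and 2.49-fold lower, and the hypoblast and yolk sac endoderm list as a whole had a median of -0.14 (5 of 14 higher and 3 lower). POSTN, LUM, COL3A1 and COL1A2 were among the 10 highest genes as well, at 7.45%, 8.06%, 12% and 19.3% of their level in extraembryonic mesoderm.

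The 10 lowest genes of the secondary yolk sac were CGA (789-fold), GUCA2A (0 UMIs on day 8), RYR3, POT1-AS1 (13.1-fold), SLC24A2, UNC5D (12.4-fold), COL9A2, L1TD1, PORCN (10.9-fold), which is needed for WNT secretion, and FST (9.62-fold), an activin inhibitor. CGA UMIs occurred in every label of day 4, at a median of 12 per SYS cell, so its fold need not mean expression by these cells. WNT targets had a median of -1.16 (-1.43 to -0.55, percentile 0.0300), with 4 of 8 lower, among them NKD1 (4.01-fold) and SP5 (3.93-fold). The NODAL pathway median was -1.56 (3 of 5 lower, NODAL 8.56-fold). Imprinted genes had a median of 0.79 (0.45 to 1.77), with H19 8.58-fold (at 9.91% of its level in extraembryonic mesoderm) and PHLDA2 4.06-fold higher and PEG10 1.75-fold lower. The unfolded protein and amino acid response had a median of 1.00, with HERPUD1 2.10-fold and DDIT3 2.03-fold higher.

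Over all cells with extraembryonic mesoderm labels, the extraembryonic mesoderm and extracellular matrix lists had higher medians on day 8 than on day 4, and the primitive streak and epithelial lists had lower ones. POSTN was at 107 and 1232 CPM (11.5-fold higher, 10.6 to 12.5), DCN at 30.1 and 261 CPM (8.67-fold higher, 7.41 to 10.2) and the interferon-induced membrane protein gene BST2 at 97.9 and 787 CPM (8.04-fold higher, 7.37 to 8.79). PDZRN4, IL1RAPL1, CLEC1B and SNHG7 were 24.9-fold, 14.3-fold, 8.67-fold and 6.97-fold higher, and the immediate early genes JUN, FOS and FOSB 8.41-fold, 6.67-fold and 7.57-fold. TAGLN, ACTA2 and MYOCD were 5.96-fold, 3.98-fold and 4.64-fold lower. NODAL was at 84.98 and 8.60 CPM (9.88-fold lower), FABP5 3.89-fold and MIR302CHG 6.70-fold lower. CGA, MT1M, MT1H and MT1G completed the 10 lowest genes (679.9-fold, 73.96-fold, 27.1-fold and 17.7-fold), from day 4 levels of MT1M and MT1H that were 26.6% and 19.5% of those in the epiblast. CGA UMIs occurred in every label of day 4, at a median of 11 per ExEM_1 cell and 11 in barcodes with at most 1000 genes. The CGA fold therefore need not mean expression by these cells.

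The extraembryonic mesoderm list had a median log2 ratio of 1.10 in these cells (7 of 13 higher), and extracellular matrix genes 0.77 (0.70 to 0.83, percentile 100.0), with COL6A3, COL6A2 and FN1 3.25-fold, 3.20-fold and 2.71-fold higher and LAMB1 at 113 and 109 CPM. HOX genes had a median of 0.89 (4 of 11 higher, and a median of 0.55 with equal weight of labels), with HOXA10 4.32-fold higher, while HOXB6 and HOXB5 were 1.80-fold and 1.77-fold lower. Cardiac muscle genes had a median of -0.73, with MYL7 3.20-fold lower and TNNI1 2.08-fold higher. Epithelial genes had a median of -1.15 (KRT18 2.87-fold lower) and primitive streak and nascent mesoderm genes -2.02 (EOMES 6.95-fold, MIXL1 4.06-fold lower, and a median of -0.84 with equal weight of labels). The amnion list had a median of -0.81, with VTCN1 80.7-fold and GABRP 37.6-fold lower, from 18.6% and 21.2% of their amnion levels, and HAND1 1.55-fold higher. That amnion median was 0.014 with equal weight for each label of the compartment and -0.12 with cells in a cluster of another compartment left out, so its direction did not hold; the epithelial median was -0.59 in the latter case. The label ExEM_4, singled out after its values were seen, carried CER1 at 124, 351 and 286 CPM and MIXL1 at 232, 333 and 139.6 CPM on days 4, 6 and 8.

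Extraembryonic mesoderm cells of the 2 days were spread differently over the clusters. The largest cluster of day 8 held 903 of them, against 42 on day 4, and the largest of day 4 held 161, against 186 on day 8. In the 2 clusters with at least 50 such cells on both days, given equal weight, the extracellular matrix median was -0.06 and the extraembryonic mesoderm median 0.34. The higher matrix list thus did not hold within those 2 clusters. They held 146 and 161 such cells on day 4, and 120 and 186 of the 2079 on day 8, so the largest cluster of day 8 is not covered. Holding the cluster fixed also removes any change that moved cells between clusters. HOX was at 0.41, primitive streak and nascent mesoderm at -0.70, epithelial at -0.62, the amnion list at 0.11 and immediate early and heat shock at 1.54. POSTN and DCN were at log2 ratios of 2.27 and 1.68, rather than 3.53 and 3.12, and TAGLN and ACTA2 at -2.81 and -3.02.

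Among amnion cells, 94 on day 4 and 130 on day 8, the BMP, WNT and FGF target lists and the HOX list had higher medians on day 8, and the syncytiotrophoblast list had a lower one. The cells of the 2 days lay largely in different clusters: 75 of day 4 were in a cluster that also held 33 trophoblast cells, against 1 of day 8, and 14 of day 4 in the cluster that held 123 of day 8. A comparison inside 1 cluster was therefore not possible with at least 50 cells, and these values do not separate a change within amnion cells from a different kind of cell under the label. PLA2G2A, a secreted phospholipase gene on chromosome 1, was at 6.97 and 724 CPM (104-fold higher, 50.2 to 259). GPC5, KRT16, MEIS2, LRRTM4, LRP1B and ART5 were 37.5-fold, 32.7-fold, 18.6-fold, 15.5-fold, 16.5-fold and 25.3-fold higher. CACNA1C and LRRC4C were 77.01-fold (21.01 to 641) and 70.1-fold (12.2 to 2802) higher from at most 2 UMIs on day 4, and CXCL14 was at least 21.1-fold higher from 0. The transcription factor ISL1 was at 28.9, 126 and 177 CPM on days 4, 6 and 8. CGA was at 14261, 2324 and 6.89 CPM on those days. Of the day 6 amnion cells with at least 5000 UMIs, 12 of 109 had a CGA UMI after thinning, against 129 of 1485 epiblast cells. The day 6 value therefore does not describe most of those amnion cells, and the 3 values need not mean a graded fall within cells. A minority of cells carried most of the day 4 level, since the median cell had 2122 CPM and 21.3% of cells were over 5000 CPM. PAGE4, CYP19A1, S100P, ADGRL3, IFI6 and MUC15 were 628-fold, 123-fold, 86.9-fold, 57.2-fold, 53.5-fold and 63.1-fold lower, and SERPINE1, CGB3 and MT1M had 0 UMIs on day 8. On day 4, 25% of the 68 amnion cells with at least 5000 UMIs carried at least 3 syncytiotrophoblast genes. CGA, a gene of that set, had a UMI in all 68, and 4.24% of day 4 epiblast cells passed the same rule.

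Of the BMP targets, 8 of 10 were higher in day 8 amnion (median 1.73, 1.48 to 2.03, percentile 100.0), with ID1 at 138 and 1143 CPM. FGF and ERK targets had a median of 1.67 (5 of 9 higher, DUSP6 4.98-fold) and WNT targets 1.14 (RNF43 5.45-fold, LEF1 4.56-fold). HOX genes had a median of 3.04 over 6 measured members, several of them from 0 to 4 UMIs on day 4, and 0.79 with no filter on low values. Their sum was highest in extraembryonic mesoderm, 443 CPM on day 8 against 164 in amnion, and the extraembryonic mesoderm list was higher in amnion as well (median 2.17, 1.92 to 2.46, 499.9 and 1493 CPM in sum). The amnion list had a median of 0.56, with TFAP2B 13.8-fold and HAND1 4.67-fold higher and GATA3 1.61-fold lower. Imprinted genes went the other way (median -1.08, -1.47 to -0.48), with CDKN1C 21.8-fold and PHLDA2 15.2-fold lower and MEST 2.04-fold higher. The syncytiotrophoblast, trophoblast and epiblast lists had medians of -5.61, -0.68 and -2.30, although POU5F1 was at 416 and 454 CPM, and CDX2 was 24.7-fold (6.52 to 209) higher. S phase genes had a median of -0.74.

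**Figure D3:**
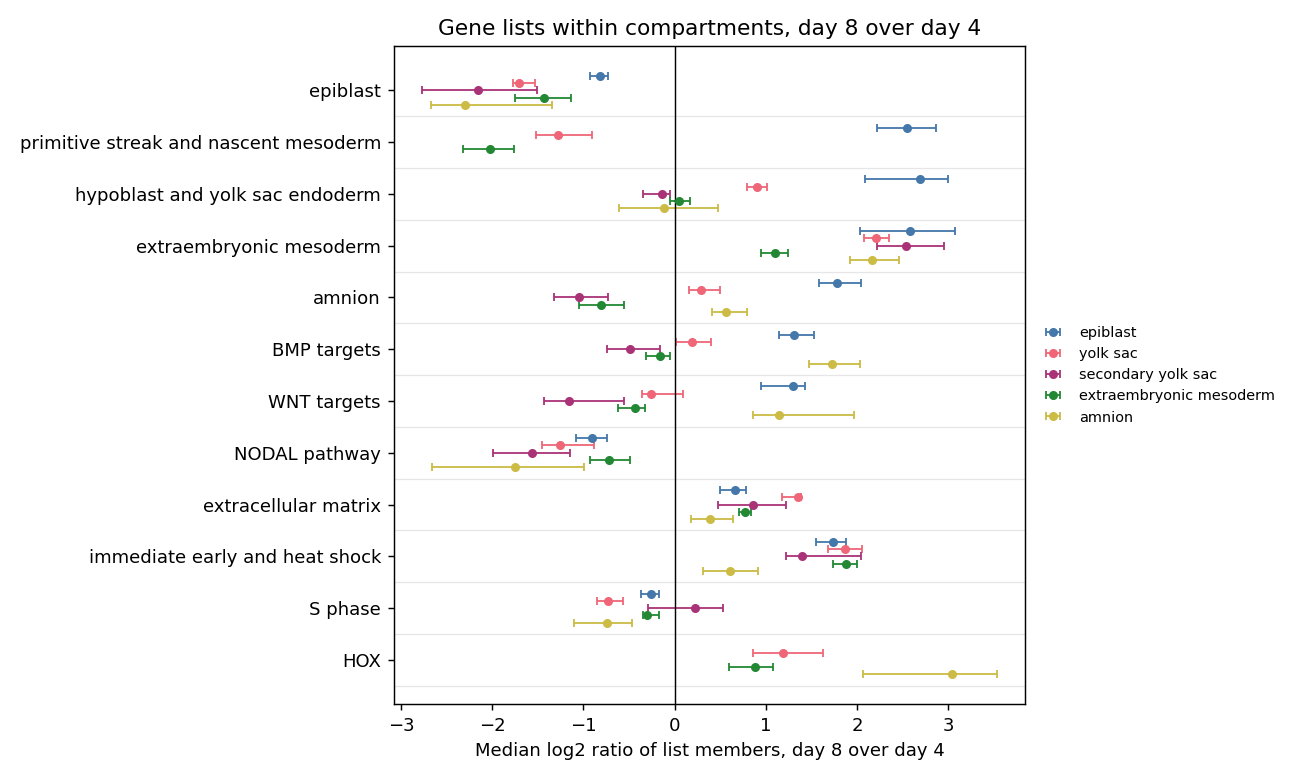
Median log2 ratio of day 8 over day 4 for the lists described, in each compartment with at least 50 cells on both days, with 95% counting intervals from Poisson draws as bars, a vertical line at no difference and 1 library per day. The extraembryonic mesoderm list lies above 0 in each compartment drawn, at 2.57 in the epiblast and 2.17 in amnion. Free RNA as a source of that list was weighed for the yolk sac alone.

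Trophoblast, the placental lineage, could be described on day 4 alone. Its 147 cells held CGA at 22261 CPM, the aromatase gene CYP19A1 at 1778 CPM, CYP11A1 at 1106 CPM, the placental growth factor gene PGF at 1284 CPM, the fusogen gene ERVW-1 at 595 CPM and the transcription factor EPAS1 at 1338 CPM. In the epiblast of the same day those genes were at 1439.9 (CGA), 10.2 (CYP19A1), 17.6 (CYP11A1), 26.7 (PGF), 8.90 (ERVW-1) and 16.9 CPM (EPAS1). TP63 and KRT7, members of the trophoblast list, were at 6.42 and 64.2 CPM in trophoblast, below the 39.8 and 127 CPM of amnion. Of these cells, 69.4% had under 5000 UMIs, against 10.2% of day 4 epiblast cells. With cells under 2000 genes or over 10% mitochondrial counts left out, the trophoblast share of day 4 was 1.56%.

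Co-detection asked how many single cells carried several genes of a rare program at equal depth. At 5000 UMIs per cell, at least 3 primitive streak genes were found in 139 of 5115 cells on day 6 (2.72%, 2.29 to 3.20%), against 3 of 2533 on day 4 (0.118%) and 20 of 2622 on day 8 (0.763%). By label, 79 of 512 ExEM_4 cells (15.4%) and 38 of 616 Posterior_Epiblast_2 cells (6.17%) carried them on day 6, and 14 of 138 Posterior_Epiblast_2 cells (10.1%) on day 8. In the epiblast as a whole the share was 2.69% on day 6 (40 of 1485) and 2.89% on day 8 (14 of 484). The anterior hypoblast set was found in 146 of 5115 cells on day 6 (2.85%, 2.42 to 3.35%), against 0.434% on day 4 and 0.305% on day 8. ExEM_4 (80 of 512 cells, 15.6%) and YS_1 (44 of 640, 6.88%) held most of the day 6 cells. ExEM_4 thus carried both sets at similar shares on that day, so the name of the set does not identify its cells as anterior hypoblast. How many cells carried both was not counted. As background, 0 of 208 secondary yolk sac cells and 0 of 109 amnion cells of day 6 carried either set at that depth, with exact upper bounds of 1.76% and 3.33%. The amnion bound lies above the day 6 shares over all cells, so it shows no lower background. ExEM_1 had 0 of 609 cells for either set (upper bound 0.604%), but YS_2 carried the primitive streak set in 8 of 646 (1.24%). Without thinning, the day 6 shares were 7.48% for primitive streak and 6.26% for anterior hypoblast.

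The germ cell set was found in 4 of 484 epiblast cells on day 8 (0.826%, 0.226 to 2.10%), 1 of 1485 on day 6 and 0 of 1464 on day 4, which allows up to 0.205%. Cells outside the epiblast carried it too: 1 of 460 yolk sac cells and 1 of 68 amnion cells on day 4, and 2 of 1286 yolk sac cells and 2 of 109 amnion cells (1.83%) on day 6. On day 8, 0 of 94 amnion and 0 of 1635 extraembryonic mesoderm cells did. Over all cells the share was 0.0790% on day 4, 0.0978% on day 6 and 0.153% on day 8, with overlapping intervals, so a difference between days was not detectable at this depth. Unthinned shares over all cells were 0.744%, 0.601% and 0.401%. In the epiblast the unthinned shares went the other way, at 0.0613%, 0.178% and 1.68% (0.809 to 3.07% on day 8), while the yolk sac had 3.58%, 1.83% and 0.680%. At least 3 syncytiotrophoblast genes were carried by 32 of 45 trophoblast cells on day 4 (71.1%), 51 of 460 yolk sac cells (11.1%), 62 of 1464 epiblast cells (4.24%) and 13 of 436 extraembryonic mesoderm cells (2.98%). Across all cells that set was at 6.95% on day 4 (5.99 to 8.01%), in 3 of 5115 cells on day 6 (0.0587%) and in 0 of 2622 on day 8, which allows up to 0.114%. Its unthinned day 4 share was 20.3%. After thinning, CGA, a set gene, had a UMI in 98.9% of day 4 epiblast, 98.9% of yolk sac and 100% of extraembryonic mesoderm cells. CGB3, another set gene, had a UMI in 17.1% of those epiblast cells. For most such cells the rule therefore asked for only 2 further set genes, and free RNA may have supplied some. The day 4 shares outside trophoblast thus do not identify cells with a syncytiotrophoblast program.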

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

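The tests for CGA reads from a few epiblast cells, for free RNA in the proportions of trophoblast cells, for free RNA from cells of any kind, for epiblast transcription as the main source of CGA, for syncytiotrophoblast cells under other labels and for free RNA from extraembryonic mesoderm were chosen only after the results were seen; the first of these replaced an earlier one, the share of epiblast CGA UMIs in the 5% of cells with most (26.5%), which decided nothing. The contrasts between compartments and the patterns weighed were also picked after the values were seen.

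List medians for day 8 over day 4 went in opposite directions in several pairs of compartments, and the difference itself was not tested. The amnion list had a median log2 ratio of 1.78 in the epiblast and -0.81 in extraembryonic mesoderm, a difference of 2.58, but the second value was 0.014 with equal weight of labels and -0.12 with cells in a Leiden cluster of another compartment left out, so the opposite direction does not hold there. Within clusters present on both days the epiblast value was 0.29. WNT targets had 1.30 in the epiblast and -1.16 in the secondary yolk sac, a difference of 2.46, but 0.07 in the epiblast within such clusters, so its higher direction does not hold there either. Imprinted genes had 0.79 in the secondary yolk sac and -1.08 in amnion, a difference of 1.87. No comparison within clusters was possible for amnion, where 75 cells of day 4 and 1 of day 8 lay in a cluster shared with trophoblast cells. The amnion value thus may reflect a different kind of cell under the label. In the secondary yolk sac, H19 was far below its level in extraembryonic mesoderm, and free RNA was not tested there.

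Barcodes that the annotation left out also carried at least 3 genes of the co-detection sets. Sets found in more than 3 such barcodes of a day are given, and with no control library no background level is known. The germ cell set was found in 4 of 2035 such barcodes on day 4 (0.197%, 0.0536 to 0.503%). On day 6 the anterior hypoblast set was in 7 of 1587 (0.441%, 0.178 to 0.907%) and the primitive streak set in 5 of 1587 (0.315%, 0.102 to 0.734%). The syncytiotrophoblast set was in 305 of 2035 on day 4 (14.99%, 13.5 to 16.6%). Depths differ too much for a direct comparison with annotated cells (medians of 708 and 10710.0 UMIs on day 4). With both thinned to 500 UMIs, 0 barcodes carried the first 3 sets on those days. Of the annotated cells, 0 of 2957 on day 4 carried the germ cell set. On day 6, 4 of 5991 annotated cells carried the anterior hypoblast set and 2 of 5991 the primitive streak set. The syncytiotrophoblast set was in 9.67% of barcodes (8.24 to 11.3%) and 1.45% of annotated cells (1.05 to 1.95%) on day 4.

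CGA UMIs occurred in every label of day 4, at a median of 12 per cell in Epiblast_1, 11 in ExEM_1 and 13 in YS_1. In day 4 barcodes with at most 1000 genes, a median of 677.5 UMIs came with a median CGA level of 16299 CPM, 15.5 times the epiblast median of 1053 CPM (14.8 to 16.3). A few doublets or misnamed cells cannot account for it, because 98.9% of day 4 epiblast cells had a CGA UMI at 5000 UMIs per cell. Free RNA with the gene proportions of the annotated trophoblast cells as its only source is argued against by the UMIs of CGB3, CYP19A1, ERVW-1, CYP11A1 and PGF per CGA UMI, which had a median ratio of 0.302 in those barcodes over trophoblast cells, from 0.139 for CYP19A1 to 1.14 for CGB3. That median is the ratio of ERVW-1, whose own counting interval was 0.262 to 0.348. Transcription by the epiblast cells as the main source in the median cell is argued against as well, because those barcodes had a median of 11 CGA UMIs against 12 in epiblast cells, a ratio of 0.917 (0.917 to 1.0). Free RNA from cells of any kind remains: CGA UMIs did not follow the other RNA of the barcodes, with a ratio of 1.0 (0.909 to 1.1) between the 25% of barcodes with most and the 25% with fewest other UMIs (medians of 1350 and 415). In epiblast cells the median rose from 10 to 16 CGA UMIs between such groups (medians of 5943 and 19223 other UMIs), less than the 4 to 20 of POU5F1 but not flat, which leaves room for a part made in the cells. Free RNA from lysed syncytiotrophoblast in particular stays open, since the lysed cells may have had other proportions. A smaller part made by the epiblast cells cannot be told apart from free RNA: CGB3 and CYP19A1 UMIs per CGA UMI, pooled, were 1.19 times those of the barcodes (1.09 to 1.30), which had been set to exclude it, but CGB3 alone was at 1.60 and CYP19A1 at 0.638, so the pooled value decides nothing. Levels over 5000 CPM were found in 48.9% of YS_2, 21.3% of amnion, 16.8% of Epiblast_4, 12.2% of YS_1, 11.7% of ExEM_3 and 8.53% of Commited_Epiblast_3 cells. Epiblast_4 cells were shallow, with medians of 9 CGA UMIs and 3107 UMIs per cell, against 12 and 13314.5 in Epiblast_1. Their share over 5000 CPM therefore need not mean more CGA UMIs per cell. For the other labels, these tests on medians do not explain such cells.

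Trophoblast labels were carried by 147 cells on day 4, 0 on day 6 and 4 on day 8. Removal by the authors' cell filter is argued against by the barcodes without annotation, of which 0.0849% on days 6 and 8 (0.0103 to 0.306%) carried at least 3 syncytiotrophoblast genes, against 14.99% on day 4, a share that free RNA may have raised. Syncytiotrophoblast cells under other labels are argued against by the 4 of 9229 annotated cells of days 6 and 8 outside those labels that carried them (0.0433%, 0.0118 to 0.111%). Loss in dissociation, a difference between the pools of models and a difference between the protocol days stay open and were not tested.

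Extraembryonic mesoderm genes were higher in yolk sac cells on day 8 than on day 4. Free RNA from extraembryonic mesoderm would reach all cells of the library alike, but at 5000 UMIs per cell the share of day 8 cells with a UMI of POSTN, DCN, COL3A1 or LUM was 6.23 to 9.13 times higher in yolk sac than in epiblast cells. Doublets or misnamed mesoderm cells and expression by yolk sac cells cannot be told apart, because the 10% of cells with most POSTN and DCN held 40.6% of the COL3A1 and LUM UMIs (38.3 to 43.0%), between the values that would have decided it. Those 30 cells had APOA1 at 2206 CPM against 11810 CPM in the other 264 yolk sac cells, medians of 17265 and 9874.5 UMIs, and a doublet score in the top 5% for 60% against 19.3%. Of the 30 cells, 83.3% were YS_2, against 17.4% of the others. Free RNA was not tested as a source of the higher extraembryonic mesoderm list in the epiblast, secondary yolk sac and amnion.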

How the results depend on the processing

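The alternatives that left out the top 5% of doublet scores, gave labels equal weight inside a compartment, left out cells in a Leiden cluster of another compartment or weighted equally the clusters with at least 50 cells of a compartment on both days were chosen after the data were seen. Across the alternatives, 1272 list medians moved by less than their counting interval, 397 by more, and 10 with an absolute value of at least 0.5 changed sign. Of the values of named genes, 848 stayed within the interval and 232 moved without reversing. These counts leave out the authors' normalized values, whose natural log differences have another unit (84 medians and 60 named genes). For shares of cells, 54 stayed within the interval and 18 moved. The values that stayed include those of an alternative that left out the called doublets, 2 cells on day 4 and 0 on days 6 and 8. It gave 217 of those list medians, 160 of those named genes and 18 of those shares, and could hardly move any value. With no filter on low values, the primitive streak and nascent mesoderm list for day 8 over day 4 reversed to 1.21 in all cells and 0.038 in the yolk sac. With compartments weighted equally, the cardiac muscle list reversed to -0.53 for day 8 over day 4 and -0.47 for day 6 over day 4, and in extraembryonic mesoderm equal weight of labels took the amnion list to 0.014. Without cells in a Leiden cluster of another compartment, hypoblast and yolk sac endoderm genes in the yolk sac reversed to -0.29. With Leiden clusters weighted equally, primitive streak and nascent mesoderm genes in the epiblast reversed to -1.69, naive pluripotency genes there to 0.44, and in extraembryonic mesoderm extracellular matrix genes to -0.057 and the amnion list to 0.11. Neither the yolk sac nor amnion had a cluster with enough cells for this. These weightings and leaving out cells alter the mix of cells by construction. The clusters are built from the same expression values, so holding them fixed or leaving out cells by cluster can also remove a change inside a cell type. The cause of the changes of sign was not tested.

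With compartments taken from 21 Leiden clusters, which kept 91.8% of cells in their own compartment, the shares on days 4, 6 and 8 were 15.2%, 21.7% and 3.86% for yolk sac, 3.11%, 6.49% and 9.19% for secondary yolk sac and 6.43%, 4.79% and 6.63% for amnion. Epiblast was at 26.1% on day 6 and 15.1% on day 8, extraembryonic mesoderm at 14.8% on day 4 and trophoblast at 0% on day 8. The stricter cell filter gave 18.1% extraembryonic mesoderm and 1.56% trophoblast on day 4. Without the top 5% of doublet scores the yolk sac held 16.4%, 23.0% and 7.31%. For day 8 over day 4 in all cells, the epiblast list was at -2.59 with TMM factors, -2.42 without mitochondrial and ribosomal protein genes, -1.06 with compartments weighted equally and -0.50 as a natural log difference of the authors' normalized values. The extraembryonic mesoderm list was at 2.45 with TMM factors, 2.60 as the mean of per-cell CPM, 1.28 with equal compartments and 0.55 as the natural log difference. BMP targets in the epiblast were at 1.06 with TMM factors, 0.75 without cells in a Leiden cluster of another compartment and 0.47 with clusters weighted equally. Hypoblast and yolk sac endoderm genes in the yolk sac were at 0.78 with TMM factors, 0.68 per cell and 1.04 without the top doublet scores, and extracellular matrix genes in extraembryonic mesoderm at 0.69, 0.52 and, with equal labels, 0.63. TMM factors shifted the median of all genes by -0.21 in all cells, -0.25 in the epiblast, -0.13 in the yolk sac, 0.11 in the secondary yolk sac and -0.12 in amnion.

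Co-detection depended on depth and on the number of genes asked for. With 2 set genes, the shares were 1.60% for germ cells on day 8, 10.2% for anterior hypoblast and 11.5% for primitive streak on day 6 and 30.3% for syncytiotrophoblast on day 4, and with cells thinned to 2000 UMIs they were 0.0311%, 0.788%, 0.453% and 5.01% in the same order.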

Other observations

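Of the metallothionein genes, MT1E, MT1F, MT1G, MT1H, MT1M, MT1X and MT2A were lower on day 8 than on day 4 in the epiblast, yolk sac, extraembryonic mesoderm and amnion, but not uniformly in the secondary yolk sac. They were picked after their values were seen, and no list of the family was tested. MT2A was at 955, 188 and 37.9 CPM on days 4, 6 and 8 in the epiblast, 430.0, 103 and 48.8 CPM in the yolk sac, 261, 111 and 98.7 CPM in extraembryonic mesoderm and 440.1, 124 and 84.4 CPM in amnion. In the secondary yolk sac MT2A was at 41.05 CPM on day 4 and 35.7 CPM on day 8, a difference not detectable at this depth (ratio interval 0.560 to 1.38), and MT1X was 1.66-fold higher (95% interval 1.01 to 2.86). MT1X was at 402, 446 and 77.6 CPM in the epiblast. On chromosome 16 these genes span 56608199 (start of MT2A) to 56684196 (end of MT1X) in GRCh38.

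Immediate early genes also differed across compartments. FOS was at 23.9, 66.3 and 127 CPM in the epiblast, 31.1, 96.4 and 259 CPM in the yolk sac, 81.99, 162 and 547 CPM in extraembryonic mesoderm and 177, 267 and 486 CPM in amnion. With 1 library per day, the handling of each pool and its biology are not separable for these genes.

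Placental genes in the label YS_2 on day 4 did not keep the proportions found in trophoblast. YS_2 had CGA at 14380.4 CPM, CGB3 at 266, CGB5 at 26.6, CGB8 at 35.1 and PGF at 343 CPM, with CYP19A1 at 19.96 and ERVW-1 at 47.8 CPM. Trophoblast cells of that day had CGA at 22261, CGB3 at 297, CYP19A1 at 1778 and ERVW-1 at 595 CPM. These genes were picked after their values were seen.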
